A study of Mus musculus with 9 samples.

How the data were processed

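Stripes of corpus, forestomach and squamocolumnar junction from 9 female C57Bl/6 mice were pooled by 3 mice into 3 series per zone, per the labels, and total RNA was extracted with Trizol. Biotin-labelled cRNA was hybridised to Affymetrix mouse expression arrays, 1 array per pool, 9 arrays in all. The deposited values are intensity signals on a linear scale, 1 per probe set, made by the authors with MAS5 per the submitters' processing notes, whose version and settings are not given in the sources used here. In the values themselves, the trimmed mean of each array (2% off each end) is 200.0, as MAS5 scaling to a common target leaves it, the largest value is 22793.5 and 3 values are 0. MAS5 uses mismatch probes for background, which leaves dim signals noisy, and bright probe sets can saturate, which compresses their folds.

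The table held 45101 probe sets, of which 64 control probe sets were left out of the tests and used only for the 3′ to 5′ ratios. The platform annotation, dated 2016, gave 1 gene symbol to 34958 probe sets, several to 932 and none to 9211. Symbols were updated by Entrez ID to the GRCm38.p6 gene table, which matched 34754. Only probe sets with 1 symbol were named, covering 18194 genes. A probe set was kept if above its array's own 40th percentile (a signal of 29.0 to 36.5) on at least 3 arrays, which left 29511, of them 24870 with 1 symbol. Each gene was represented by its kept probe set with the highest mean log2 value, giving 13637 genes. For 6462 genes with more than 1 kept probe set, another probe set was called the opposite way in 694 (forestomach against corpus), 155 (junction against corpus) and 409 (junction against forestomach) genes, and for Prkaa2 in the first of these. Red blood cell genes had 1 measured member and were not tested. Muc6 was not among the genes tested. No genomic coordinates are given.

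Values were analysed as log2(signal + 9.8), the pseudocount being the median over arrays of the 20th percentile, without further normalization. A fold here is on that scale and understates the change of dim genes. Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per zone over all 9 arrays, moderated two-sided tests (6 residual and 2.56 prior degrees of freedom), and Benjamini-Hochberg adjustment over the genes with a threshold of 0.05. Genes above or below both neighbours were found by an intersection-union test, which takes for each gene the larger p of both junction comparisons when both differences have the same sign. Lists were tested with camera at its preset correlation of 0.01 and with an estimated correlation, adjusted over 31 lists. The lists, 32 in all, hold markers of the cell types of the stomach wall and its neighbours, and pathways of squamous and glandular tissue, of which 783 of 948 members known to the reference were measured. The position of the junction is the median over genes of (junction minus corpus) over (forestomach minus corpus) on the linear scale within a series. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, and estimated correlations used statmod 1.5.0.

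The comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. Named genes are the 12 largest changes in each direction between forestomach and corpus and the 8 largest in each direction for the junction against each neighbour, among genes past the threshold whose arrays of both zones do not overlap. For genes above both neighbours they are the 20 with the largest smaller difference and for genes below both up to 10, with all 3 junction arrays beyond the other 6. For each list they are up to 4 members past the threshold with the largest difference, and a fixed set of reference genes such as Krt5, Atp4a and Lgr5 is named whatever its values. Predicted genes, Riken clones and genes without a standard symbol were passed over in naming but counted. The last 7 genes above both, and the uncalled Krt6b, were named after their values were seen.

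Arrays of the same series come from the same pools of mice, so the series number pairs them, and a fit with the series as a block was an alternative. Deviations from the zone means correlated at r from -0.0287 to 0.123 between arrays of one series (mean 0.0329, 9 pairs, 1 over 0.1), against a mean of -0.0165 over 18 pairs of different series. Deviations within a zone cancel out by construction. The mean for different series therefore follows closely from that for the same series and is no separate benchmark. Further alternatives were other pseudocounts (1 and 30.9), no or a stricter filter, quantile normalization, median centring, the mean of a gene's probe sets, all probe sets, limma with trend and robust options, only the 6 arrays compared, a 2-fold minimum, intersected lists, and leaving out each array and each series. Leaving out forestomach arrays 2 and 3 together, the Fisher test of lists, the split of genes by brightness and the position per list were added after seeing the data. No array was left out of the main results.

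The scripts were tested on simulated data with 13637 genes drawn from the real means and spread, 200.0 of them changed. For forestomach against corpus, limma recovered 28.4% of 1.5-fold, 65.7% of 2-fold and 92.4% of 4-fold changes, for junction against corpus 41.8%, 79.1% and 92.4%, for junction against forestomach 34.3%, 74.6% and 92.4%, and above both neighbours 34.3%, 58.2% and 95.5%. False calls among 13437 unchanged genes were 12, 7, 10 and 2, out of 136, 149, 144 and 127 genes called. In the real data 8168, 3406, 6079 and 27 genes were called in the same order. The cut-off after adjustment depends on how many genes change, so the shares recovered here need not hold for the real data. In a junction simulated as a mixture of its neighbours the intersection-union test called 0 genes above and 0 below both, and intersecting both lists called 9 and 5. Camera called the 1 shifted list of 31 and 0 random ones. The simulated genes varied independently of each other. The simulation therefore cannot test camera on lists whose members vary together, such as smooth muscle with an estimated correlation of 0.618.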

Results

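Gene expression was measured in 3 adjoining zones of the stomach of healthy female C57Bl/6 mice at 3 months of age. The corpus is the acid-secreting glandular part, and the forestomach is the non-glandular part of the rodent stomach, lined by stratified squamous epithelium. The squamocolumnar junction is the line where both epithelia meet, and it corresponds in the mouse to the human gastro-esophageal junction. A stripe of each zone, 600 to 800 µm wide and lying side by side, was taken from 9 mice. Tissue of 3 mice went into each of 3 series, so each zone had 3 arrays and arrays of the same series came from the same mice. The series are separate pools of mice, so the spread between the 3 arrays of a zone holds biological as well as technical variation. The median signal of an array lay between 47.9 and 57.1, and the number of arrays limits the precision of every value. The comparisons address how the glandular and the squamous tissue differ, how the junction differs from each of them, which genes lie above or below both in the junction, and where between its neighbours the junction lies.

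Arrays grouped by zone. Across genes, which are not independent replicates, arrays of one zone correlated at r = 0.975 or higher, whereas the mean r was 0.739 between corpus and forestomach, 0.900 between corpus and junction and 0.870 between forestomach and junction. The first principal component took 73.4% of the variance and placed the junction arrays between those of the neighbours, and the second took 14.6% and set the junction apart from both.

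**Figure D1:**
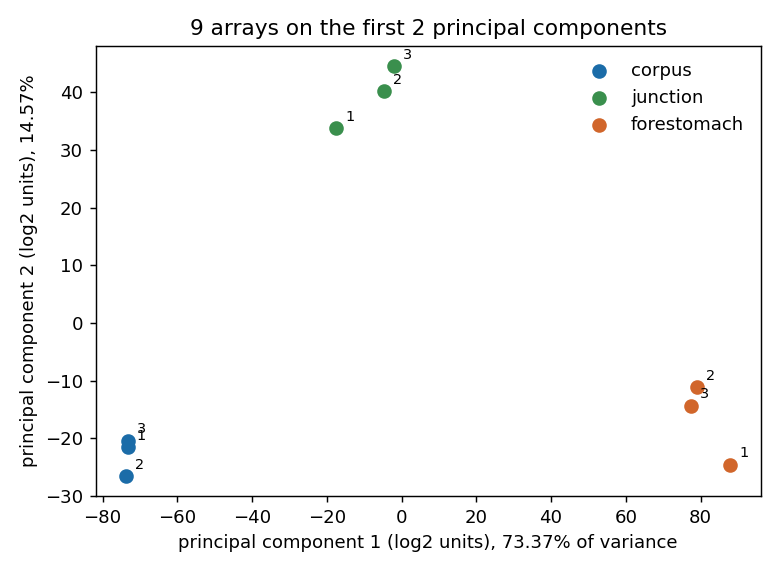
Principal components of the 9 arrays over the genes tested, with the first component (73.4% of the variance) on the horizontal and the second (14.6%) on the vertical axis, 1 point per array coloured by zone. The junction arrays lie from -17.4 to -2.12 on the first axis, between corpus arrays near -73.2 and forestomach arrays from 77.4 to 88.0.

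The first comparison asked how the 2 tissues that meet at the junction differ. Genes of the cornified layer, the dead outer sheet of squamous epithelium, were among the largest rises in the forestomach. Hornerin (Hrnr), a protein of the cornified envelope, was 202-fold above the corpus (log2 difference 7.66 ± 0.25, SE, adjusted p = 1.09e-07). Cystatin E/M (Cst6), a protease inhibitor of keratinocytes, went from a signal of 28.0 ± 7.27 to 5575 ± 285 (mean ± SD, n = 3 each, 149.8-fold, adjusted p = 7.07e-08). The 12 largest rises named also held the aldehyde oxidase Aox4 (234-fold), the keratinocyte caspase Casp14 (188-fold), and the late cornified envelope genes Lce3c, Lce1c and Lce1m (177-, 149- and 133-fold). The others were the skin protease Klk7 with its inhibitor Spink5 (142- and 139.7-fold), Lipm (144-fold), Bpifc (134-fold) and the neuropeptide gene Nmu (137-fold). Secreted products of the gastric glands were among the largest falls. Pepsinogen C (Pgc) was 136-fold higher in the corpus than in the forestomach (log2 difference, forestomach minus corpus, -7.09 ± 0.67, adjusted p = 2.52e-05). Intrinsic factor (Cblif), which binds cobalamin, was 129.7-fold higher (adjusted p = 6.91e-04), and the hunger hormone ghrelin (Ghrl) 109.8-fold (adjusted p = 1.11e-05). Tmed6 (224-fold), the hepcidin gene Hamp2 (187-fold), transthyretin (Ttr, 166-fold), Pdia2 (156-fold) and Apoa1 (126-fold) were also lower in the forestomach. The same held for Clic6 (122-fold), Smim38 (108-fold), the potassium channel subunit Kcne2 (107-fold) and the gastric claudin Cldn18 (91.5-fold). The sizes of most of these falls rest on single forestomach arrays, so their order is open. Without array 1, Ttr, Pdia2, Pgc, Cblif, Apoa1, Clic6, Ghrl, Smim38 and Cldn18 were 100.4-, 97.0-, 77.6-, 42.4-, 61.4-, 50.3-, 64.6-, 57.7- and 37.8-fold lower. Without array 3, Pgc, Cblif, Apoa1, Clic6 and Smim38 were 242-, 269-, 206-, 215- and 186-fold lower, and without array 2 Cldn18 was 149-fold lower. Leaving out a series moved 10 of the 12 falls by over 1.5 times, to between 37.9- and 298-fold, among them Hamp2 without series 3 (281-fold), and without arrays 2 and 3 together all 12 lay between 164- and 1218-fold. Klk7 was 91.5-fold higher without corpus array 2 and 89.1-fold without series 2, and with the mean of a gene's probe sets Casp14 was 22.9-fold higher and Smim38 40.6-fold lower. A pseudocount of 1 or 30.9 (the larger one) moved 9 of the 12 rises (to between 49.4- and 759-fold) and 6 of the falls (up to 358-fold), so these folds describe the scale used. For each of these 24 genes all 3 arrays of one zone lay above all 3 of the other, as the rule for naming requires.

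Marker lists followed the same division. Of the 41 cornification genes measured, 38 rose, 1 fell and 2 did not pass (39 and 1 adjusted over the list alone). Gsdma had a log2 difference of 6.89 and filaggrin (Flg), which bundles keratin, one of 6.77. Of the 22 genes of the squamous basal layer 14 rose, 4 fell and 4 did not pass (15 and 4 adjusted over the list alone), among them the desmosome protein Pkp1 (6.86), keratin 14 (Krt14, 6.55), Col17a1 (6.06) and Trp63 (5.62), the p63 gene of squamous progenitors. Their camera adjusted p were 7.09e-18 and 6.16e-04, and adjusted p = 0.277 with an estimated correlation for both. Among parietal cell genes 19 of 21 fell and 1 rose (1 and 19 adjusted over the list alone), among them the subunits of the gastric proton pump, Atp4a (-5.61) and Atp4b (-5.87). All 12 chief cell genes measured fell, also when adjusted over the list alone, among them the acidic chitinase Chia1 (-5.74) and Pga5 (-5.04). Of the 25 surface and neck mucous cell genes 21 fell and 1 rose (1 and 23 adjusted over the list alone), among them Agr2 (-6.34), Muc1 (-6.23) and the surface mucin Muc5ac (-5.94). Camera adjusted p were 7.31e-08, 1.50e-05 and 1.68e-07 for these lists, and adjusted p = 0.277 with an estimated correlation for each. Simple epithelium genes such as Krt8 (-5.04), Krt18 (-4.94) and the transcription factor Hnf4a (-5.20) fell in 16 of 23 and rose in 4 (4 and 16 adjusted over the list alone, camera adjusted p = 6.16e-04, and adjusted p = 0.400 with an estimated correlation). Without forestomach array 1 the log2 differences of Atp4a, Atp4b, Chia1, Agr2, Muc1, Muc5ac, Krt8 and Hnf4a were -4.55, -4.75, -4.42, -5.21, -5.37, -4.58, -4.13 and -4.56, and without series 1 they lay between -5.37 and -4.09. Without array 3 those of Atp4a, Atp4b, Chia1 and Muc5ac were -6.33, -6.67, -6.95 and -6.69, without array 2 that of Muc5ac was -6.56, and without series 3 those of these 4 genes and Agr2 lay between -7.13 and -6.50. Without arrays 2 and 3 together the log2 differences of the first 8 genes and Krt18 lay between -8.67 and -5.75. The mean of a gene's probe sets gave 5.26, 5.52, 3.95 and -3.74 for Gsdma, Krt14, Trp63 and Hnf4a, and pseudocount 1 and the larger one gave 7.78 and 5.89 for Gsdma, 7.30 and 4.92 for Col17a1, -6.86 and -5.56 for Muc1 and -5.81 and -4.47 for Hnf4a. With the larger one Pkp1 was at 6.21 and Trp63 at 4.93. Corpus transcripts were not equally low on the forestomach arrays. The median corpus-high parietal cell gene reached 0.588%, 2.70% and 5.04% of its corpus signal on arrays 1, 2 and 3, the median chief cell gene 0.464%, 2.70% and 5.53%, and the median mucous cell gene 0.412%, 3.66% and 3.76%. Tff1, whose forestomach signal was 470.1, 5625 and 6219 on arrays 1, 2 and 3, did not pass (log2 difference -1.98 ± 0.85, adjusted p = 0.0729). Without forestomach array 1, 2 or 3 it passed (adjusted p = 0.0268, 0.0437 or 0.0346), and the highest adjusted p over its alternatives was 0.163. Its log2 difference ranged from -2.84 to -0.584 when an array or a series was left out. Without forestomach arrays 2 and 3 together it was -4.40.

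Lists of deeper tissue layers and of metabolism moved as well. All 24 smooth muscle genes measured rose in the forestomach (also adjusted over the list alone, median log2 difference 1.46), among them Synpo2 (2.58), Ldb3 (2.36) and desmin (Des, 2.32), the last 2 at 1.47 and 1.27 with the mean of their probe sets. Fibroblast and matrix genes rose in 30 of 34 and fell in 0 (31 and 0 adjusted over the list alone), with the collagens Col14a1 at 2.06 and Col1a1 at 1.73. Nerve and glia genes rose in 14 of 21 and fell in 2 (14 and 3 adjusted over the list alone). The camera adjusted p values were 7.67e-09, 7.31e-08 and 0.0265, and adjusted p = 0.277 with an estimated correlation for each. Of the 39 genes of oxidative phosphorylation 37 fell and 0 rose (the same counts adjusted over the list alone), by a median log2 difference of -0.82, led by the succinate dehydrogenase subunits Sdhd (-2.12) and Sdhb (-1.54). Enteroendocrine genes fell in 14 of 18 and rose in 2 (2 and 14 adjusted over the list alone), with somatostatin (Sst) at -6.08 and chromogranin A (Chga) at -4.16. By camera, adjusted p was 6.81e-11 and 6.16e-04, and adjusted p = 0.277 with an estimated correlation for both. The 3′ to 5′ signal ratio of the Gapdh control probe sets, a measure of RNA integrity, was 0.846 ± 0.071 (SD, n = 3) in the forestomach, 0.723 ± 0.029 in the corpus and 0.759 ± 0.0043 in the junction. That of actin was 1.65 ± 0.08, 1.65 ± 0.08 and 1.52 ± 0.038. For every gene named here as changed, all 3 arrays of one zone lay above all 3 of the other.

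In all, 8168 of 13637 genes (59.9%) differed between forestomach and corpus by limma, 4085 higher and 4083 lower in the forestomach, and 3485 of them by 2-fold or more. The arrays of both zones did not overlap for 9050 genes, where chance gives 10% of the genes tested. Of the 31 lists tested, camera called 18 with its preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.273, 4 lists at an unadjusted p under 0.05).

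**Figure D2:**
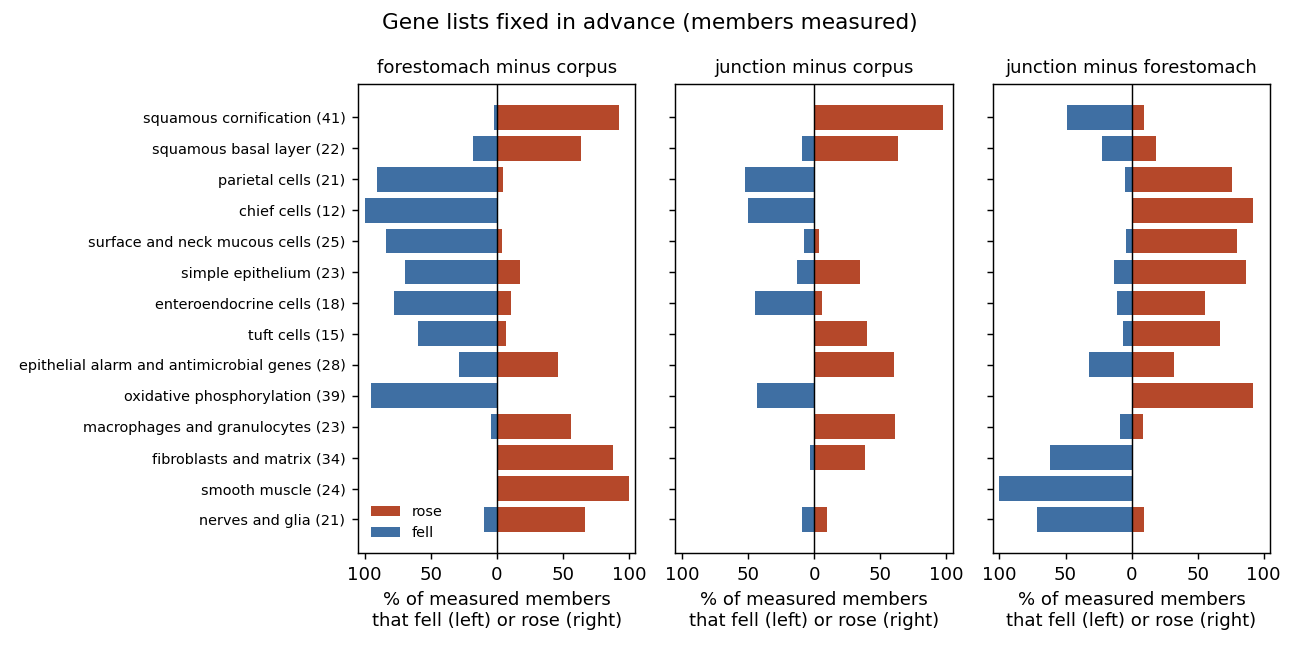
Percent of the measured members of 14 gene lists that rose (bars to the right) or fell (bars to the left) in each of the 3 comparisons between zones, at a limma adjusted p under 0.05. Cornification genes rose in 38 of 41 in the forestomach and 40 of 41 in the junction against the corpus, and smooth muscle genes fell in all 24 in the junction against the forestomach.

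The second comparison asked what the junction holds that the glandular tissue beside it does not. Keratins and cornified envelope genes were among the largest rises. Keratin 6b (Krt6b), a keratin of stressed and fast-growing squamous epithelium, was 130.2-fold above the corpus (log2 difference 7.02 ± 0.58, adjusted p = 5.00e-05). Krt14, a keratin of basal cells, went from a signal of 57.2 ± 22.2 to 6049 ± 1045 (93.5-fold, adjusted p = 9.52e-07). Lce3c (115-fold), Lce3a (93.3-fold), Lce1c (87.7-fold), Crct1 (77.3-fold), Pkp1 (76.9-fold) and Hrnr (75.2-fold) rose as well. Falls were smaller. Neuritin (Nrn1) was 4.59-fold lower (log2 difference -2.20 ± 0.17, adjusted p = 3.66e-05), and the monocarboxylate transporter gene Slc5a8 4.2-fold. The fatty acid transporter gene Slc27a2 was 4.16-fold lower, the DNA helicase gene Blm 4.14-fold, Speer4cos 4.63-fold and Wbscr25 3.75-fold. The cholecystokinin receptor gene Cckar (3.66-fold, adjusted p = 0.00496) and Cyp2u1 (3.64-fold, adjusted p = 0.00636) also fell. Both lost the call without series 2 (adjusted p = 0.0882 and 0.0699, the highest over their alternatives, with the lowest at 2.26e-04 and 9.62e-04). Krt6b was 79.6-fold higher without corpus array 2 and 82.4-fold without series 2, Lce3c 199.9-fold without series 1, and Krt14 37.0-fold with the mean of its probe sets. With pseudocount 1 and the larger one Krt6b was 199- and 79.4-fold higher, and with the larger one Pkp1 was 49.0-fold and Hrnr 45.5-fold higher. Speer4cos, Slc5a8, Slc27a2, Wbscr25 and Cyp2u1 lay below the filter level on all 3 junction arrays, so the sizes of these falls and their order depend on the pseudocount, and the other pseudocounts moved 4 of them to between 2.12- and 7.59-fold. The main products of the gastric glands were not shown to differ from the corpus, though their errors were wide. The log2 differences were -0.19 ± 0.75 for Atp4a, -0.28 ± 0.67 for Pgc and -0.26 ± 1.13 for Cblif. Those of Muc5ac and the trefoil gene Tff2 were -0.43 ± 0.94 and 0.18 ± 0.83. None of them passed the threshold (adjusted p from 0.774 to 0.895). The fit shares its variance across all zones, so these errors also hold the spread of the forestomach arrays. The signal of Atp4a ran from 45.6 to 644.6 on those arrays. It ran from 9336.9 to 13487.5 in the corpus and from 9754.1 to 10999.9 in the junction. The width of these errors therefore does not show that the corpus or junction arrays vary widely. For each gene named as changed, all 3 junction arrays lay on one side of all 3 corpus arrays, as the rule for naming requires.

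Among the lists, 40 of 41 cornification genes rose and 0 fell in the junction (the same counts adjusted over the list alone), and of the 22 basal layer genes 14 rose, 2 fell and 6 did not pass (14 and 2 adjusted over the list alone), with keratin 15 (Krt15) at a log2 difference of 5.63 and Col17a1 at 5.59. Krt15 was at 5.04 without series 2 and Col17a1 at 6.20 without series 1, and pseudocount 1 and the larger one gave 6.29 and 4.82 for Krt15 and 6.83 and 4.46 for Col17a1. These lists had camera adjusted p of 5.78e-40 and 8.63e-09, and adjusted p = 0.0699 with an estimated correlation for both. Genes of tight junctions, gap junctions and desmosomes rose in 18 of 36 and fell in 3 (19 and 6 adjusted over the list alone), led by Dsc1 (5.69) and connexin 26 (Gjb2, 5.19), with camera adjusted p = 5.83e-06, and adjusted p = 0.0814 with an estimated correlation. Parietal cell genes fell in 11 of 21 and rose in 0 (0 and 14 adjusted over the list alone), for example the anion exchanger gene Slc26a7 (-1.27). Chief cell genes fell in 6 of 12 and rose in 0 (1 and 6 adjusted over the list alone), for example Gper1 (-1.58) and Nupr1 (-1.11). Camera gave adjusted p of 1.95e-04 and 0.0290, and adjusted p = 0.349 and 0.438 with an estimated correlation. Of the 25 mucous cell genes only Aqp5 (1.45, adjusted p = 0.00283, 0.0535 without series 3, range 1.11e-04 to 0.0535 over its alternatives) rose and 2 fell, and camera made no call (adjusted p = 0.516). The spread of the forestomach arrays also enters the tests of these glandular genes. Members that did not pass are therefore not shown to equal the corpus. Simple epithelium genes rose in 8 of 23 and fell in 3 (8 and 3 adjusted over the list alone), with the claudin Cldn2 at 3.77 and keratin 7 (Krt7) at 2.36. Cldn2 was at 3.11 without corpus array 2, 3.13 without series 2, 2.61 with the mean of its probe sets, and 4.48 and 3.03 with pseudocount 1 and the larger one. Their camera adjusted p was 0.0528 (0.0497 with the series as a block, range 0.0497 to 0.178 over the other alternatives, and adjusted p = 0.575 with an estimated correlation). The junction and stem cell list had 8 of 25 genes rise and 2 fall (8 and 5 adjusted over the list alone), with keratin 17 (Krt17) at 5.39 (6.04 without series 1, 6.19 and 4.45 with pseudocount 1 and the larger one), Cd44 at 3.07 and the progenitor factor Sox2 at 1.83. The intestinal stem cell receptor Lgr5 did not pass (-0.26 ± 0.43, adjusted p = 0.695). For the list as a whole the camera adjusted p was 0.0460, 0.0552 with the series as a block, and adjusted p = 0.209 with an estimated correlation. Pseudocount 1, quantile normalization and median centring also ended the call (0.0523, 0.0654 and 0.0893, range 0.0400 to 0.0893 over the other alternatives). Oxidative phosphorylation genes fell in 17 of 39 and rose in 0 (0 and 22 adjusted over the list alone, camera adjusted p = 1.09e-06, and adjusted p = 0.380 with an estimated correlation). Limma called 0 of 24 smooth muscle genes (2 higher and 1 lower at an unadjusted p under 0.05, camera adjusted p = 0.722).

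Limma called 3406 genes (24.98%), 1800 higher and 1606 lower in the junction, and 953 by 2-fold or more (753 of them higher). At 8-fold or more it called 204 higher and 0 lower, also 0 lower at an unadjusted p under 0.05. With pseudocount 1 or the larger one 247 or 154 were higher by that much. A stripe that mixes its neighbours keeps part of each corpus level, which limits falls on a log scale but not rises. This split alone therefore does not show an asymmetry of the junction itself. The arrays did not overlap for 5968 genes, against 10% by chance, and camera called 19 lists (0 with an estimated correlation, lowest adjusted p = 0.0699, 7 lists at an unadjusted p under 0.05). Without junction array 3 the count was 2233, and without series 1, 2 or 3 it was 2028, 1221 or 1314. Centring each array on its median turned the split to 2110 higher and 873 lower, and moved the median log2 difference of all genes from -0.05 to 0.05 here and from -0.01 to 0.10 between forestomach and corpus, where it gave 4616 higher and 3386 lower.

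The third comparison set the junction against the squamous tissue beside it. Products of the gastric glands were among the largest rises, with Pgc 112-fold above the forestomach (log2 difference 6.81 ± 0.67, adjusted p = 7.54e-05), and Cblif 108-fold (adjusted p = 0.00146). Also higher were Smim38 101-fold, Ttr 89.5-fold and Apoa1 87.4-fold. Secretory genes Bpifb1 (101-fold), Clca1 (95.3-fold) and Agr2 (95.1-fold), the last a protein disulfide isomerase of mucus-secreting cells, rose alongside them. The sizes and the order of these rises rest on single forestomach arrays. Without array 1, Pgc, Cblif, Bpifb1, Smim38, Agr2, Ttr and Apoa1 were 63.9-, 35.3-, 38.7-, 53.8-, 43.5-, 54.2- and 42.6-fold higher. Without array 3, Pgc, Cblif, Bpifb1, Smim38 and Apoa1 were 199.5-, 224-, 168-, 174- and 143-fold higher, and without array 2 Bpifb1 was 161-fold higher. Leaving out a series moved the same 7 to between 33.5- and 221-fold, and leaving out arrays 2 and 3 together to between 244- and 1013-fold. With the mean of their probe sets Smim38 and Agr2 were 24.4- and 62.1-fold higher. Clca1 was 306-fold higher with pseudocount 1 and 39.2-fold with the larger one, and both also moved Bpifb1 (174 and 66.9) and Ttr (138 and 57.6). Cblif was 177-fold higher with pseudocount 1. Genes that fell included Skint10 (7.45-fold lower, log2 difference -2.90 ± 0.16, adjusted p = 2.92e-06), Kcnip2 (6.53-fold), Rdh9 (6.52-fold) and Serpinb7 (6.12-fold). Without junction array 1 Kcnip2 was 10.2-fold lower and without series 1 9.80-fold, against 3.87-fold with the mean of its probe sets and 4.09-fold with the larger pseudocount. The acute phase gene Orm1 (adjusted p = 2.57e-04), the activity-induced transcription factor Npas4 (adjusted p = 1.81e-04) and Rbmxl2 (adjusted p = 8.56e-05) fell to below the filter level on all 3 junction arrays, so the pseudocount sets the size of their falls. They were 8.73-, 6.84- and 6.46-fold lower with the pseudocount used, 17.4-, 14.5- and 11.5-fold with pseudocount 1 and 4.6-, 3.66- and 3.61-fold with the larger one. Plcxd1 fell 6.17-fold (log2 difference -2.62, adjusted p = 4.61e-05), and 3.25-fold with the mean of its probe sets. With pseudocount 1 its log2 difference was -0.83 and the call was lost (adjusted p = 0.207, range 6.03e-07 to 0.207 over its alternatives). Of the 22 basal layer genes 4 rose and 5 fell (4 and 5 adjusted over the list alone), and camera made no call (adjusted p = 0.946). The keratins of that list did not pass. Krt5 had a log2 difference of 0.09 ± 0.30 (adjusted p = 0.825) and Krt14 of -0.00154 ± 0.25 (adjusted p = 0.997), and Krt15 was at 1.01 ± 0.49 (adjusted p = 0.130). The suprabasal keratins Krt4 (-0.65 ± 0.34, adjusted p = 0.152) and Krt13 (-0.44 ± 0.32, adjusted p = 0.293) did not pass either. Krt4 passed with only the 6 arrays compared (0.0111) and without corpus array 3 (0.0182, range 0.0111 to 0.433 over its alternatives), and Krt13 with the mean of its probe sets (0.00929, range 0.00929 to 0.632). Trp63 was lower in the junction (-0.54 ± 0.18, adjusted p = 0.0413, 0.0724 with the series as a block, range 0.0149 to 0.252 over its alternatives). That call also ended without corpus array 2 (0.0534), any forestomach array (0.0800 to 0.103), junction array 1 or 2 (0.123 and 0.0825), or series 1 or 2 (0.184 and 0.20). Pseudocount 1, no filter, the mean of its probe sets and leaving out forestomach arrays 2 and 3 ended it too (0.0726, 0.0645, 0.108 and 0.252). For each gene named as changed, all 3 arrays of one zone lay above all 3 of the other, which the rule for naming requires of the largest changes.

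The glandular lists were higher in the junction. Parietal cell genes rose in 16 of 21 and fell in 1 (17 and 1 adjusted over the list alone), and chief cell genes in 11 and 0 of 12 (the same counts adjusted over the list alone). Mucous cell genes rose and fell in 20 and 1 of 25 (22 and 1 adjusted over the list alone) and simple epithelium genes in 20 and 3 of 23 (the same counts adjusted over the list alone). Examples are Atp4b (5.63), the scavenger protein gene Dmbt1 (5.70), Muc1 (5.83) and Krt20 (4.72). Without forestomach array 1 these were 4.50, 4.74, 4.96 and 4.11 and without series 1 4.44, 4.77, 4.90 and 4.12. Atp4b was at 6.43 without array 3 and 6.43 without series 3, Dmbt1 at 6.36 without array 2 and 6.43 without series 2, and Muc1 at 6.46 without series 3. Without arrays 2 and 3 together they were 7.88, 7.63, 7.55 and 5.92. Pseudocount 1 and the larger one gave 6.49 and 5.00 for Dmbt1 and 6.45 and 5.16 for Muc1. Camera adjusted p were 3.64e-08, 2.95e-06, 5.48e-10 and 5.24e-09, and adjusted p = 0.259 with an estimated correlation for each. The forestomach arrays 2 and 3 carry more corpus transcripts than array 1, and the Gapdh ratio is highest in the forestomach. Of the 41 cornification genes 20 fell and 4 rose (4 and 22 adjusted over the list alone, camera adjusted p = 0.00149, and adjusted p = 0.669 with an estimated correlation). The 4 that rose were Krt6a (3.88, and 4.48 without forestomach arrays 2 and 3), Krt6b (3.36, and 4.08) and Krt16 (3.02), keratins known from wound edges and hyperproliferative epithelium, and the desmosomal cadherin Dsc2 (2.68). Of the 33 cell cycle genes 13 rose and 1 fell (13 and 0 adjusted over the list alone, camera adjusted p = 0.00415, and adjusted p = 0.697 with an estimated correlation), among them Ube2c (1.70) and Birc5 (1.29). The proliferation marker Mki67 (0.98, adjusted p = 0.00922) lost its call without series 1 (0.0890, range 0.00219 to 0.0890 over its alternatives). All 24 smooth muscle genes fell (also adjusted over the list alone, median -1.47), with Lmod1 at -2.35. So did 21 of 34 fibroblast and matrix genes and 15 of 21 nerve and glia genes (22 and 15 adjusted over the list alone), and 0 and 2 rose. The camera adjusted p values were 1.06e-11, 9.84e-06 and 6.23e-04, and adjusted p = 0.259 with an estimated correlation for each. Oxidative phosphorylation genes rose in 36 of 39 and fell in 0 (the same counts adjusted over the list alone, camera adjusted p = 8.39e-11, and adjusted p = 0.259 with an estimated correlation).

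Limma called 6079 genes (44.6%), 2927 higher and 3152 lower in the junction, and 2047 by 2-fold or more. At 8-fold or more, 218 were higher (289 with pseudocount 1 and 161 with the larger one) and 1 was lower (8 and 0). A stripe that mixes its neighbours also limits falls against the forestomach. The arrays did not overlap for 7612 genes, against 10% by chance. Camera called 14 lists (0 with an estimated correlation, lowest adjusted p = 0.259, 4 lists at an unadjusted p under 0.05). Without series 1 the count was 3946, and without forestomach arrays 2 and 3, an alternative chosen after seeing the data, 3805.

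The junction was then searched for genes that exceed both neighbours, which a stripe that only mixes its neighbours would not hold. Keratin 6a (Krt6a) stood furthest out, at a signal of 70.2 ± 25.9 in the corpus, 117 ± 40.3 in the forestomach and 1822 ± 432 in the junction (mean ± SD, n = 3 each), 14.7-fold above the higher neighbour (adjusted p = 0.00395). Its partner keratin Krt16 reached 635 ± 147 in the junction, 8.09-fold above the higher neighbour (adjusted p = 0.0253). The chloride channel gene Cftr reached 217 ± 37.5 against 25.7 ± 10.1 in the corpus and 18.4 ± 6.50 in the forestomach (6.50-fold, adjusted p = 0.00562). Wfdc2 reached 1279 ± 77.8 against 402 ± 70.3 and 291 ± 25.7 (3.16-fold, adjusted p = 0.00395). The membrane mucin Muc4 (5.08-fold, adjusted p = 0.00418), the gasdermin Gsdmc2 (3.15-fold, adjusted p = 0.0132) and keratin 79 (Krt79, 2.96-fold, adjusted p = 0.00196) also stood above both. So did the claudin Cldn7 (4.2-fold), the amino acid transporter gene Slc6a14 (3.09-fold) and the GABA receptor subunit gene Gabrp (2.56-fold). Further genes above both were Chil3 (7.53-fold), a chitinase-like protein of macrophages, the neutrophil antigen Cd177 (3.96-fold), Alox15 (3.39-fold) and Alox5ap (2.26-fold) of eicosanoid synthesis, the lectin Clec7a (2.22-fold), Rgs13 (4.26-fold) and Lrmp (2.04-fold). The neuropeptide gene Calcb (5.16-fold), Tnmd (3.55-fold) and the apelin receptor gene Aplnr (2.71-fold) completed the 20 named, and the adjusted p of those without a printed value lay between 0.0183 and 0.0440. All 3 junction arrays lay above all 6 others for each of them, as the rule for naming requires. The other 7 called were Capg, Cd300lf, Cdhr2, Cx3cl1, Pla1a, Ugt8a and Wnt5a. Only Prkaa2 (1.74-fold, log2 difference -0.80, adjusted p = 0.0388) and the imprinted gene Peg3 (1.69-fold, adjusted p = 0.0183) lay below both. With the mean of its probe sets Prkaa2 had a log2 difference of -0.29 (adjusted p = 0.589, range 0.00398 to 0.589 over its alternatives). Without forestomach arrays 2 and 3 Krt6a was 22.4-fold above both, and Chil3 5.01-fold with its call lost (adjusted p = 0.429, range 0.0103 to 0.680 over its alternatives). Krt6b (10.2-fold, adjusted p = 0.0733), Krt17 (6.59-fold, 0.0519) and Krt7 (1.94-fold, 0.0848) lay above both without passing.

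By the intersection-union test 27 genes were above both neighbours and 2 below both (283 and 429 at an unadjusted p under 0.05), and 20 of the 27 by 2-fold or more. Of the 27, 12 were higher in the corpus than in the forestomach, 2 were higher in the forestomach and 13 were not called between them. Counted without a test, all 3 junction arrays lay above the other 6 for 389 genes and below them for 521, where chance gives 1.19% of the genes for each. Of the fixed lists, cornification held Krt6a and Krt16 (2 of 41) and tuft cells Alox5ap and Rgs13 (2 of 15), adjusted p = 0.0458 and 0.0121 by a one-sided Fisher's exact test chosen after seeing the data. With the series as a block 12 genes were above both, 11 of them among the 27, and 0 below both (459 at an unadjusted p under 0.05 by limma). Among named genes the block ended the calls of Cldn7, Alox15 and Alox5ap (adjusted p = 0.160 each), Gabrp (0.113), Wnt5a (0.0976), Tnmd, Slc6a14 and Prkaa2 (0.0898 each), Clec7a (0.0843), Lrmp (0.0762), Peg3 (0.0660) and Cd177 (0.0553). Over all their alternatives the adjusted p of these genes ranged from 6.82e-04 to 0.650. Without corpus array 1, forestomach array 3, or junction array 1, 2 or 3 the count above both was 13, 12, 9, 8 or 6. Without forestomach arrays 2 and 3 together it was 8, and without series 1, 2 or 3 it was 1, 0 or 0 (224, 228 and 204 at an unadjusted p under 0.05). The count below both ranged from 0 to 3 when arrays or series were left out. Over 21 alternative settings Krt6a kept the threshold in 19 and Cftr, Gsdmc2, Krt79, Muc4 and Wfdc2 in 18. Aplnr, Calcb, Cd177 and Tnmd kept it in 13, Lrmp in 12, Krt16, Wnt5a and Peg3 in 11, Chil3, Cldn7, Gabrp and Rgs13 in 8, Alox15 and Clec7a in 7, Alox5ap in 6, Slc6a14 in 6 of 20 and Prkaa2 in 4. None of these genes kept it in all of them, and each kept its direction.

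**Figure D3:**
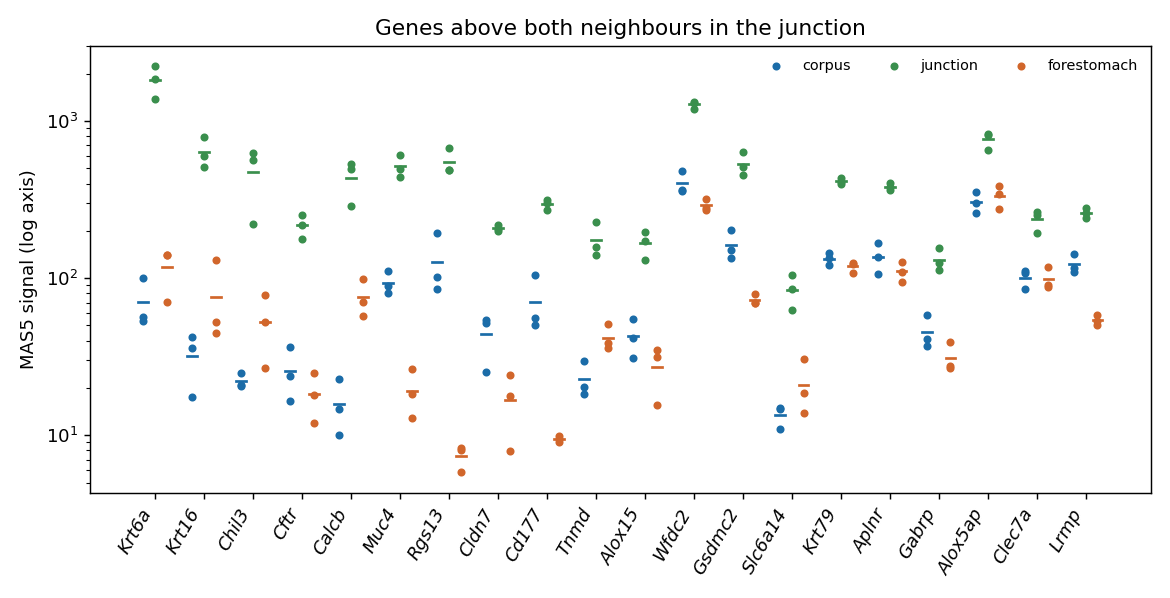
MAS5 signal on a logarithmic axis of the 20 named genes above both neighbours, with 1 point per array, a short bar for the mean of 3 arrays, and colours for corpus, forestomach and junction. Krt6a reaches 1822 ± 432 in the junction against 70.2 ± 25.9 in the corpus and 117 ± 40.3 in the forestomach.

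The last comparison placed the junction on a linear scale between corpus (0%) and forestomach (100%), with genes that differ at least 8-fold between them. By the median of 314 forestomach-high genes, such as Hrnr and Krt14, the junction lay at 41.4% ± 10.4 (SD, n = 3 series), with 29.7%, 44.8% and 49.6% in series 1, 2 and 3. By the median of 285 corpus-high genes, such as Pgc and Atp4a, it lay at 34.3% ± 7.0, with 26.6%, 36.0% and 40.3%. The junction mean lay between both neighbours for 3208 of 4085 forestomach-high genes (78.5%) and 3442 of 4083 corpus-high genes (84.3%). The position was computed without a test.

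**Figure D4:**
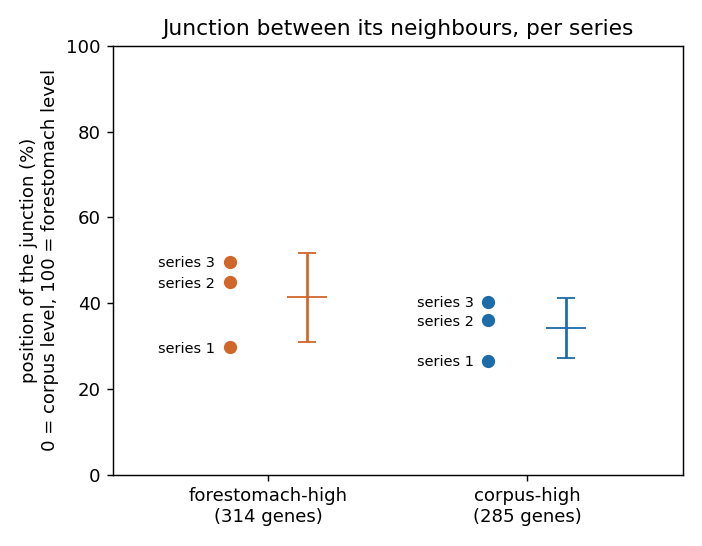
Position of the junction in percent of the way from corpus (0) to forestomach (100), 1 dot per series, with mean and SD bars, for 314 forestomach-high and 285 corpus-high genes. Forestomach-high genes place it at 41.4% ± 10.4 and corpus-high genes at 34.3% ± 7.0.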

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

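The tests of array scaling, muscle, connective tissue, neighbouring RNA and signal compression in this part were chosen only after the result was seen, and the counts of splits of the arrays were planned.

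The first pattern is the 27 genes above both neighbours, led by Krt6a, Krt16 and Cftr. Against a common shift of the junction arrays, all genes had a median log2 difference of -0.0497 against the corpus and -0.04 against the forestomach. The called genes had a median of 1.63. The arrays had been scaled to a trimmed mean of 200 beforehand, so these medians cannot show whether that scaling was right. With quantile normalization or median centring, 34 or 36 genes lay above both, all 27 among them. Against muscle carried with the stripe, the smooth muscle list had a median of -1.47 against the forestomach (interquartile range 0.794). Against connective tissue as the cause of these genes as a set, the fibroblast list had a median of -0.538 there, below their 1.63 by more than its interquartile range of 0.611, with 0 of 34 genes risen and 21 fallen, although its median against the corpus was 0.357. Of 100 assignments drawn from 840, 5 (the real one included) gave at least 27 genes above both, and 5 gave at least the real 2 below both, so this count does not exclude chance. The highest other results, 1824 above and 2205 below, and all 4 others as large came from assignments with the 3 arrays of another zone in the junction's place, which points to the zones as the structure of these arrays, and assignments that mixed zones there gave at most 0 by limma (104 above and 236 below at an unadjusted p under 0.05, against 283 and 429 in the real one). Cells particular to the junction, or a local response of its epithelium, stay open and may account for these genes, and neither was tested.

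The second pattern is that forestomach arrays 2 and 3 carry more corpus transcripts than array 1, for example Atp4b at 44.4, 396 and 771 and Muc5ac at 21.2, 472 and 565 on arrays 1, 2 and 3. Against array scaling or background, genes with no called difference between the tissues had a median log2 shift of 0 on arrays 2 and 3 (5469 genes, interquartile range 0.374), while 33 corpus-high members of the parietal, chief and mucous lists had one of 2.23. A factor common to all genes would move both sets alike. The arrays had been scaled to a common trimmed mean beforehand, so the shift of 0 alone cannot show whether that scaling was right. Over all 285 corpus-high genes, a first form of this test that decided nothing and was replaced, the shift was 0.463, and 64.2% were higher on both arrays than on array 1, at a median of 2.59%, 4.49% and 5.11% of the corpus signal on arrays 1, 2 and 3. In the lists in which the pattern was seen, 11 of 11 parietal, 7 of 8 chief and 13 of 14 mucous members were higher on both arrays. Outside these lists 60.3% of the 252 other corpus-high genes were higher on both, between the bounds set for bearing out and for excluding the cause tested. The dimmest of 3 equal parts of all corpus-high genes had corpus signals from 90.6 to 599. A few percent of such a signal lies at or under the filter level of 29.0 to 36.5, where a rise is hard to see. The test therefore cannot decide whether RNA of neighbouring glandular tissue in those pools is the cause. That RNA and a biological difference between the pools, which was not tested, cannot be told apart, since no value here separates them.

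The third pattern is that bright genes of either neighbour hold more of their level in the junction than dim ones. The part held is counted from the level in the other neighbour up to that in the tissue where the gene is high. In the brightest of 3 equal parts by signal, corpus-high genes kept 74.7% ± 5.87 and forestomach-high genes 47.9% ± 10.4 (SD, n = 3 series), which add up to 123% ± 8.02, while the dimmest parts add up to 101% ± 1.90 and the middle ones to 102% ± 1.74. Signal compression at high levels predicts a sum that grows with brightness, and this sum does, so compression could draw the junction level of the brightest genes nearer to that of the tissue where they are high. Cells in the junction that truly hold more of these transcripts stay open and were not tested.

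Among probe sets outside the named genes, 5 without a single gene name lay above both neighbours and 8 below both by the same test, in data the comparisons of genes do not use. With 10 splits of 6 arrays a share under 0.05 cannot be reached. Only 1 split, the real one, gave as many genes in each comparison, with 8168 genes between forestomach and corpus against at most 0 in another split by limma (278 at an unadjusted p under 0.05), 3406 between junction and corpus against at most 1, and 6079 between junction and forestomach against at most 0 (489 at an unadjusted p under 0.05). The real split parts all 3 pairs of each series, as 4 of the 10 splits do. Outliers within zones were not tested, since each zone has 3 arrays.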

How the results depend on the processing

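Leaving out forestomach arrays 2 and 3 together was chosen after seeing the data, and the tests under all other settings were planned. The pairwise counts stayed within 1.5 times of their value under every setting run except the following. All probe sets gave 15592 calls (forestomach against corpus), 5625 (junction against corpus) and 11024 (junction against forestomach), because more features were tested, and a 2-fold minimum gave 3485, 953 and 2047 by its construction. Junction against forestomach fell to 3805 without forestomach arrays 2 and 3. When arrays or series were left out, counts ranged from 6471 to 8138, from 1221 to 3319 and from 3946 to 5979 in the same order, from 0 (without series 2) to 21 above both, and from 0 to 3 below both. The position ranged from 31.6% to 38.9% for corpus-high and from 37.3% to 47.7% for forestomach-high genes when series were left out. In that order it was 31.1% and 41.7% at a 16-fold minimum, 35.7% and 39.2% at a 4-fold minimum and 35.7% and 41.7% with quantile normalization, within 1 SD of the main value under each of these settings.

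Genes above both neighbours numbered 12 with the replicate block, 12 with pseudocount 1, 67 with the larger pseudocount (all 27 among them), 16 without the filter, 50 with the stricter filter, 43 with the mean of a gene's probe sets, 41 with all probe sets, 50 with trend and robust options, 182 with both lists intersected and 8 without forestomach arrays 2 and 3. Genes below both numbered 0 (block, 459 at an unadjusted p under 0.05 by limma), 1 (pseudocount 1), 8 (larger pseudocount), 1 (no filter), 9 (stricter filter), 1 (median centring), 11 (all probe sets), 14 (trend and robust), 0 (2-fold minimum, 429 unadjusted), 194 (intersected) and 0 (without forestomach arrays 2 and 3, 333 unadjusted). Intersecting applies no joint adjustment, and the cause of the other changes was not tested.

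Only uncalled results reversed, for lists in the direction camera gives. Krt14, junction minus forestomach, was 0.105 without forestomach arrays 2 and 3, and ranged from -0.166 to 0.113 when arrays or series were left out (0.0857 without forestomach array 2, 0.113 and 0.0136 without junction array 1 and 2, 0.0601 and 0.101 without series 1 and 2). Krt5 ranged from -0.00199 without junction array 3 (-0.000888 without series 3) to 0.219. Junction minus corpus, Tff1 ranged from -0.0853 without series 3 to 0.442, and with quantile normalization Krt19 was -0.0710 and the smooth muscle mean -0.0141. The block turned camera's direction for the Hedgehog and BMP list and left its means at -0.202 (forestomach minus corpus) and 0.160 (junction minus forestomach). For lymphocytes the direction turned at a mean of -0.0128 with pseudocount 1 and 0.0670 with quantile normalization in the first of these and 0.126 with quantile normalization in the other, and among these means only 0.0670 differs in sign from the main one. Of the other values, 612 of named genes lost and 15 gained the threshold while 9619 did not change, and for lists 60 were lost, 9 gained and 483 did not change. Blocking lost the alarm list between forestomach and corpus (adjusted p = 0.0743) and gained cell cycle in junction against corpus (0.0374) and stress genes in junction against forestomach (0.0475). Apart from these and the blocked values given with the results, it lost the calls of 8 list members (Sst, Muc13, Mcm2, Chrd, Rxrb and Uchl1 in junction against corpus, Batf3 in forestomach against corpus and Kdr in junction against forestomach, adjusted p from 0.0504 to 0.0826) and changed no other named call.

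Lists were run with the block, both pseudocounts, quantile normalization, median centring and an estimated correlation only. Leaving out a single array drops its series from the position, so this was not run apart. Where a zone keeps 1 array, that array is assumed to vary like the others. Signal near background limits folds of dim genes such as Rgs13, at 7.37 ± 1.37 in the forestomach, under the pseudocount of 9.8.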

Other observations

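The tests of tuft cell genes and the position per list were chosen only after the result was seen. The lists below were planned.

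Genes of epithelial defence and of immune cells were among those higher in the junction than in the corpus. Of 28 alarm and antimicrobial genes 17 rose, 0 fell and 11 did not pass (19 and 2 adjusted over the list alone), with the calprotectin subunits S100a9 (6.00) and S100a8 (3.39) and lactotransferrin (Ltf, 4.02) among them (log2 differences). Camera gave adjusted p = 3.50e-08, and adjusted p = 0.0699 with an estimated correlation. Between forestomach and corpus 13 rose and 8 fell (adjusted p = 0.0384, 0.277 with an estimated correlation, 0.0743 with the block, 0.0515 with pseudocount 1, 0.0710 with median centring, range 0.0268 to 0.0743), and between junction and forestomach 9 rose, led by the immunoglobulin receptor Pigr (5.55), and 9 fell (adjusted p = 0.867). Macrophage and granulocyte genes rose in 14 of 23 against the corpus (15 and 1 adjusted over the list alone), such as the eosinophil lectin Siglecf (1.56), and antigen presentation genes in 7 of 16 (9 and 0 adjusted over the list alone), such as H2-Ab1 (1.32) and Cd74 (1.03). By camera, adjusted p was 6.58e-06 and 6.98e-05, and adjusted p = 0.305 and 0.207 with an estimated correlation. The same lists had 13 and 8 genes rise in the forestomach (13 and 1 adjusted over the list alone for macrophages, adjusted p = 0.00623, 0.451 with an estimated correlation, and 0.0824 for antigen presentation, 0.0491 with quantile normalization, range 0.0491 to 0.0886), and neither was called between junction and forestomach (0.946 and 0.417). Mast cell genes rose in 8 of 14 and fell in 2 against the forestomach (8 and 2 adjusted over the list alone, adjusted p = 0.00549, 0.259 with an estimated correlation), with the mucosal proteases Mcpt1 (4.30) and Mcpt2 (5.18) up and Mcpt4 (-2.19) of connective tissue mast cells down (a call lost without forestomach arrays 2 and 3, adjusted p = 0.0529, range 2.64e-05 to 0.0529), and were not called in the other comparisons (0.0730 and 0.308, the first 0.0468 with median centring, range 0.0468 to 0.0840). For every gene named in this paragraph all 3 arrays of one zone lay above all 3 of the other.

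Wnt pathway genes rose in 26 of 43 and fell in 7 in the forestomach (26 and 7 adjusted over the list alone), with Wnt4 (3.58), Wnt10a (3.22) and Sfrp2 (3.36), and rose in 16 and fell in 2 in the junction against the corpus (17 and 5 adjusted over the list alone), with Apcdd1 (2.35). These lists had camera adjusted p of 8.19e-04 and 3.62e-04, and adjusted p = 0.273 and 0.0898 with an estimated correlation. Foregut and Hox transcription factors rose in 25 and fell in 10 of 44 in the forestomach and rose in 16 and fell in 4 in the junction against the corpus (25 and 10 adjusted over the list alone, then 16 and 5 adjusted over the list alone), with Hoxc8 (6.35 and 4.58) and Grhl3 (5.33 and 4.04) in both. Camera gave adjusted p of 0.00954 and 0.00236, and adjusted p = 0.273 and 0.0699 with an estimated correlation. Retinoid pathway genes rose in 9 of 19 and fell in 0 against the corpus (9 and 2 adjusted over the list alone, adjusted p = 0.00477, 0.0814 with an estimated correlation), led by the retinoic acid binding protein Crabp2 (5.92), and xenobiotic metabolism genes in 12 and 4 of 45 (12 and 6 adjusted over the list alone, adjusted p = 0.0220, 0.209 with an estimated correlation, 0.101 with quantile normalization, range 0.0173 to 0.101). Between forestomach and corpus neither was called, with 9 retinoid genes higher and 5 lower (adjusted p = 0.384) and 20 xenobiotic genes higher and 15 lower (0.346). Against the forestomach none of these 4 lists was called in the junction, with 7 Wnt genes higher and 18 lower (0.0589, 0.0492 with median centring, range 0.0492 to 0.0591), 11 and 23 transcription factors (0.182), 6 and 5 retinoid genes (0.871) and 15 and 18 xenobiotic genes (0.946). Adjusted over the list alone, these 6 pairs were, in the order given, 9 and 6, 21 and 17, 7 and 19, 13 and 24, 7 and 6, and 16 and 19. Hedgehog and BMP genes went both ways in each comparison (14 rose and 16 fell in the forestomach, with Shh at -5.05, adjusted p = 0.909), and there the median (0.09) differed in sign from the mean (-0.20) and the test. Such differences in sign also held, without a call, for that list, the retinoid, transcription factor, cell junction, macrophage, adipocyte and endothelial lists between junction and forestomach, and for smooth muscle between junction and corpus. For every gene named in this paragraph all 3 arrays of one zone lay above all 3 of the other.

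Other lists are given as counts of genes that rose and fell, with camera adjusted p, in the order forestomach against corpus, junction against corpus and junction against forestomach. Stress genes had 15 and 2 of 25 (0.00881), 9 and 1 (0.00362) and 1 and 7 (0.0786), with adjusted p = 0.450 and 0.429 with an estimated correlation for the first pair. The last of these became a call with the series as a block (0.0475, range 0.0475 to 0.0843). Pancreatic acinar genes, of which 2 of 13 are in another list and 12 lie above the filter level on all corpus arrays, had 0 and 11 (7.76e-05), 1 and 5 (0.0403, 0.112 with pseudocount 1, range 0.00573 to 0.112) and 10 and 0 (6.74e-05), with adjusted p = 0.273, 0.305 and 0.259 with an estimated correlation. Enteroendocrine genes in both junction comparisons had 1 and 8 of 18 (0.00339) and 10 and 2 (0.00228), with adjusted p = 0.305 and 0.259 with an estimated correlation. Fibroblast genes against the corpus had 13 and 1 of 34 in the junction (2.50e-04, and adjusted p = 0.336 with an estimated correlation). The junction and stem cell list had 8 and 13 of 25 (0.453) and, in the last comparison, 11 and 8 (0.119). Cell cycle had 3 and 12 of 33 (0.120) and, in the second, 1 and 1 (0.136, with a call at 0.0374 with the series as a block, range 0.0374 to 0.207). Cell junctions had 20 and 13 of 36 (0.103) and, in the last, 15 and 13 (0.784). Under the main settings no call was made in any comparison for interferon response (3 and 13, 1 and 4, 13 and 3 of 29, lowest 0.0980), lymphocytes (4 and 4, 2 and 0, 2 and 3 of 14, lowest 0.502), skeletal muscle (3 and 0, 0 and 0, 0 and 2 of 14, lowest 0.134), adipocytes (2 and 5, 1 and 3, 3 and 2 of 12, lowest 0.0524, with a call at 0.0484 with the larger pseudocount, 0.0494 with quantile normalization and 0.0161 with median centring, range 0.0161 to 0.0569) and endothelial cells (4 and 8, 1 and 2, 5 and 3 of 19, lowest 0.363).

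By list, the junction held different parts of the level in the tissue where the list's genes are at least 8-fold higher. Each part is counted from the level in the other neighbour up to that in this tissue. Parietal cell genes held 46.2% ± 5.89 of their corpus level (SD, n = 3 series, 11 genes), chief cell genes 87.7% ± 15.6 (8 genes), mucous cell genes 82.2% ± 5.02 (14 genes) and simple epithelium genes 82.7% ± 6.12 (13 genes). Cornification genes held 53.5% ± 10 of their forestomach level (35 genes) and basal layer genes 77.8% ± 15.8 (9 genes). These are medians over genes and do not hold for each member. Atp4a, brighter than the median parietal cell gene, had junction signals within the range of its corpus signals. The differences between lists were not tested. Over all corpus-high and all forestomach-high genes the brightest ones held more of their level than the dimmest, and the lists differ in brightness, at a median signal in that tissue of 2811 (parietal), 7462 (chief), 4157 (mucous), 1787 (simple epithelium), 5939 (cornification) and 1651 (basal layer). The parts held do not follow brightness throughout. Basal layer genes are dimmer than cornification genes but held more, and simple epithelium genes are dimmer than parietal cell genes but held more. Chief cell genes, the brightest list, held the largest part.

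Hypothesis: the junction stripe may hold more tuft cells, chemosensory cells of the gut lining, than either neighbour. Tuft cell genes rose in 6 of 15 and fell in 0 against the corpus (6 and 1 adjusted over the list alone), and rose in 10 and fell in 1 against the forestomach (10 and 1 adjusted over the list alone), where they had fallen in 9 and risen in 1 against the corpus (1 and 9 adjusted over the list alone). Camera adjusted p were 0.00744, 9.37e-05 and 0.0172, and adjusted p = 0.209, 0.259 and 0.277 with an estimated correlation. The test left out the called genes Alox5ap and Rgs13. The median of the smaller log2 difference over the other 13 genes was 0.388, above 0 in 9 of them, against a median of -0.329 over 10000 random lists matched on mean expression, at the 100th percentile, with the caveat that random lists ignore that members of a list vary together. Members include Dclk1 (1.21 against the corpus and 2.76 against the forestomach), whose first call is lost without series 2 (adjusted p = 0.0788, range 3.65e-04 to 0.0788 over its alternatives), and Trpm5 (0.32 and 1.84) and Pou2f3 (-0.03 and -0.32), which did not pass against the corpus. Of the 15 measured genes 1 is in another list, and 13, 8 and 15 lie above the filter level on all corpus, forestomach and junction arrays, so most are also expressed in the corpus. Other cells that share these genes, such as leukocytes expressing Alox5ap and Spib, stay open. The random lists also do not compare tuft cell genes with other epithelial genes. Simple epithelium genes had a mean log2 difference of 0.531 against the corpus and 3.03 against the forestomach, beside 0.554 and 1.66 for tuft cell genes. Adjusted over the list alone, 6 of 23 simple epithelium genes and 5 of 15 tuft cell genes lay above both. This test therefore does not set tuft cells apart from simple epithelium as a whole.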
